A study of Rattus norvegicus with 12 samples.

How the data were processed

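Pineal glands of Sprague-Dawley rats, wild type or of the DN-Fra-2 transgenic line, were taken at mid-day (zeitgeber time 7) and mid-night (zeitgeber time 19) under 14 h of light and 10 h of dark. Biotinylated cRNA from 10 ug total RNA of pooled glands was measured on 1-colour Affymetrix rat arrays, 3 for each of the 4 groups and 12 in all. The number of glands in a pool and the sex of the rats are not given. The deposited values are in the unit intensity, not on a log scale, and were made by the authors with MAS5 (version and settings not given). On every array the mean of the middle 96 percent of the probe sets was 100.02, so the authors' scaling had already set a common level, and no further normalization was applied. Detection calls were not in the table.

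The table held 15923 probe sets, of which 57 were Affymetrix controls and were left out of all tests. Of the other 15866, 12789 were annotated to 1 gene symbol, 312 to several and 2765 to none, and together they stood for 10412 genes. Symbols were taken from the current gene table through the gene identifier of the platform annotation. No genome was used, so no positions of probes or genes are given, and the annotation does not tell whether the Fosl2 probe set also detects the transgene. Where a gene has several probe sets, the one with the highest mean log2 value stood for it in the lists and in the naming of genes.

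Values were analysed as log2 of intensity plus 16, and fold changes are 2 to the power of differences on this scale. A probe set was tested when at least 3 arrays reached the median of the table (46.6). This kept 8602 probe sets (54.2%) of 6465 genes. Linear models were fitted with limma 3.58.1 in R 4.3.3, with a mean per group over all 12 arrays, empirical Bayes moderation with an intensity trend, 8 residual degrees of freedom and a prior of 5.90. Adjusted p values are Benjamini-Hochberg values over the tested probe sets, and a probe set was called under 0.05. The contrasts were night against day in each genotype and over both, the difference of the night change between genotypes (interaction), and DN-Fra-2 against wild type at each time and over both. Values beside ± are the SD of 3 arrays. With 3 arrays per group their number limits the precision.

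The 32 gene lists were written, and the tests, filter, naming rule and a set of other settings chosen, before the data were examined. The lists covered melatonin synthesis, adrenergic and cAMP signalling, AP-1 family, cAMP-induced and immediate early genes, circadian clock, phototransduction, pineal transcription factors, thyroid and retinoid, glucocorticoid response, MAP kinase feedback, metal handling, ER chaperones, heat shock, cholesterol synthesis, glycolysis, ribosomal proteins, oxidative phosphorylation, potassium channels, cell cycle, and receptors of neurotransmitters and peptides (acetylcholine, GABA, glutamate, dopamine, VIP and melatonin). The other lists were markers of pinealocytes, microglia and macrophages, astrocytes, endothelium, fibroblasts and meninges, oligodendrocytes, Schwann cells, neurons, choroid plexus, erythrocytes, muscle and sex. Lists were tested with limma's camera on 1 probe set per gene with a preset correlation of 0.01, and again with a correlation estimated per list. P values were adjusted over the 27 lists with at least 3 tested members. "Adjusted over the list alone" means Benjamini-Hochberg over the members only.

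Genes were named by a fixed rule. Of probe sets with 1 symbol, an adjusted p under 0.05, no overlap of the arrays of the groups compared (not asked for the interaction) and a brighter group at or above the table median, the 15 largest rises and 15 largest falls were named for wild type. For each other comparison up to 10 and 10 were named, and for each list up to 4 members with the smallest adjusted p. Fosl2, Aanat, Tph1, Asmt, Dio2, Crem, Per1, Mat2a and Nr4a1 were always looked up, and no probe set carried the symbol Tph1. The size of the night change was compared over probe sets called in the mean of both genotypes, with genotype permuted within each time.

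Whether replicate numbers pair the arrays was checked by correlating deviations from the group means. Between genotypes at mid-night the r values of arrays with the same number were 0.546, 0.341 and 0.502, all above those with other numbers. At mid-day they were 0.215, 0.400 and 0.0852 between genotypes, also all above those with other numbers. Between day and night within a genotype they fell on both sides of 0. Numbers were taken to pair arrays only where every r of arrays with the same number was above 0.1, which held between genotypes at mid-night alone. Only the value of 0.0852 kept mid-day below this level. With the choroid plexus marker Folr1 as a covariate the r values were 0.228, 0.367 and 0.142 at mid-night. At mid-day they were then 0.223, 0.378 and −0.0378, so the 2 times differed less. A block for replicate number within each time was added, and its results at mid-day and over both times are given as those of another setting only. The reported fits had no such block, at mid-night too, so the mid-night calls do not use the pairing. Nothing says that the pools of a group came from separate animals, so p values measure the spread between these pools, which may be technical.

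The method was tested on simulated data with the spread of these arrays. Of probe sets set to change 2-fold, 92.5% were recovered for night against day in wild type, 91.0% in DN-Fra-2 and at each time between genotypes, 98.5% between genotypes over both times, and 67.2% for the interaction. At 1.5-fold the interaction recovered 28.4%. Each simulated contrast held 67 probe sets changed 1.5-fold, 67 changed 2-fold and 66 changed 4-fold. The real interaction had 1 call and the real genotype comparisons 10, 10 and 15. With more true changes the Benjamini-Hochberg cut-off is looser, so recovery in these real comparisons may be lower than simulated. Wrong calls made up 2.23% to 7.69% of calls. A simulated list raised by 0.5 on the log2 scale was called in each contrast and 0 of 27 unchanged lists were. The simulated values were independent between probe sets, whereas the estimated correlation of the real choroid plexus list was 0.593. The simulation therefore cannot show how often lists with correlated members are called wrongly. With other assignments of genotype to the real arrays a median of 2 lists was called. A size ratio set to 0.8 was found as 0.796.

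The other settings chosen in advance were pseudocounts of 1 and 64, no filter, a filter at the 75th percentile (130), moderation without trend, quantile normalization, fitting only the arrays of the groups compared, a replicate block over all groups, a per-list correlation, limma's fry, and leaving out each array in turn. Settings added after seeing the data were Folr1 as a covariate, the replicate block within each time, leaving out each array for the lists, the lists without Fosl2, and the comparison of only those splits that part all 3 same-numbered pairs of mid-night arrays. Other splits of the arrays were counted in full where there were 10, and as 100 draws where there were 200.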

Results

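Gene expression in the rat pineal gland was measured on 12 Affymetrix arrays, 3 in each of 4 groups. Wild-type rats and rats of the DN-Fra-2 line, a transgenic line that carries a dominant negative form of the AP-1 transcription factor Fra-2 (the product of Fosl2), were each sampled at mid-day (zeitgeber time 7) and at mid-night (zeitgeber time 19) under 14 h of light and 10 h of dark. Each array held RNA of pooled glands, and the labels call the 3 arrays of a group triplicates. The median intensity of an array lay between 43.8 and 49.9, and the number of arrays limits the precision of every comparison. Across 8602 probe sets that passed the filter, the largest component of variation (57.6% of the variance) parted the 6 mid-night arrays from the 6 mid-day arrays. Correlations between arrays of the same group were 0.963 to 0.981. The ratios of 3' to 5' signal lay between 1.16 and 1.53 for actin, between 1.06 and 1.25 for GAPDH and between 1.72 and 2.78 for hexokinase. Fold changes below are on the scale of intensity plus 16, which draws the fold of dim probe sets towards 1.

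Which genes change between day and night in the pineal gland was asked in wild-type rats. Aanat, whose product is the enzyme that sets the daily rhythm of melatonin synthesis, rose 36.0-fold at mid-night, from an intensity of 28.2 ± 6.78 to 1565 ± 90.7 (SD, n = 3). Slc15a1, an oligopeptide transporter, rose 33.7-fold, from 15.8 ± 0.921 to 1058 ± 123 (SD, n = 3). Hs3st2, a heparan sulfate sulfotransferase, was the gene with the largest named fall, from 533 ± 104 to 55.1 ± 5.28 (SD, n = 3), a log2 change of −2.93. By limma, 2088 probe sets changed, 919 higher and 1169 lower at mid-night, and at 2-fold or more 241 were higher and 94 lower.

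The other genes with the largest night rises by the fixed rule in wild type took in signalling and transcription genes with log2 changes between 2.84 and 3.33. They were Cd24, Nap1l5, the kinase gene Sik1, the insulin receptor substrate gene Irs2, the IgE receptor gene Fcer1a, Htr2c, the phosphodiesterase gene Pde10a, the transcriptional co-activator gene Cited4, the MAP kinase phosphatase gene Dusp1, Mfrp, Sostdc1, the dopamine receptor gene Drd4 and Zrsr2-ps1. Irs2 rose from 39.9 ± 8.42 to 528 ± 18.5 and Drd4 from 90.1 ± 14.8 to 766 ± 88.8 (SD, n = 3). The other named falls, with log2 changes between −2.43 and −1.45, were those of the phosphatase gene Ptpn21, Lnc215, Hook1, the kinase gene Sgk1, Atf7ip, Psd, Mrps27, Egf, Cmya5, Tle1, Pla2g4a, Cacnb2, the short-wavelength cone opsin gene Opn1sw and Ndrg1. Egf fell from 88.3 ± 0.706 to 18.5 ± 4.93 and Opn1sw from 175 ± 32.5 to 51.8 ± 3.62 (SD, n = 3). Among the genes always named, Crem rose 11.8-fold, 6.53-fold and 3.63-fold on its 3 probe sets, Nr4a1 6.71-fold and the clock gene Per1 by a log2 change of 1.73. Adjusted p values of the 30 named genes ran from 5.9e-13 for Slc15a1 to 0.0152 for Sostdc1.

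Htr2c, Mfrp and Sostdc1 stood apart from the other named rises in their spread. Sostdc1, a secreted inhibitor of BMP and Wnt signalling, was at 39.8 ± 2.91 by day and 542 ± 361 by night, and Mfrp at 16.1 ± 5.96 and 276 ± 167 (SD, n = 3). Folr1, a marker of choroid plexus chosen for this purpose after values were seen, moved with them, at 48.3 ± 3.54 by day and 233 ± 128 by night in wild type, with 156 ± 112 and 159 ± 112 in DN-Fra-2 (SD, n = 3). With the Folr1 value of each array as a covariate, an alternative chosen after the values were seen, the calls of Htr2c and Sostdc1 were lost (adjusted p = 0.0544 and 0.260) and that of Mfrp was kept (adjusted p = 0.0116). With this covariate 1248 probe sets were called in wild type, of which 1135 were among the 2088, and of the 241 that were at least 2-fold higher at night 38 were no longer called. Of the other choroid plexus markers Prlr followed Folr1 within groups with Pearson's r = 0.956, and Otx2, Aqp1, Kcne2 and Ttr with r = 0.637, 0.599, 0.531 and 0.382. Ttr lay close to the highest values of the arrays, so its r says little. In a choroid plexus list added later, which held Htr2c, Mfrp and Sostdc1, r ran from 0.670 for Ptgds to 0.994 for Ace. Over all tested probe sets 73 besides Folr1 followed it within groups with r above 0.9. Of these, 40 were called in wild type, 31 of them at least 2-fold higher at night, and 2 were called in DN-Fra-2.

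**Figure D1:**
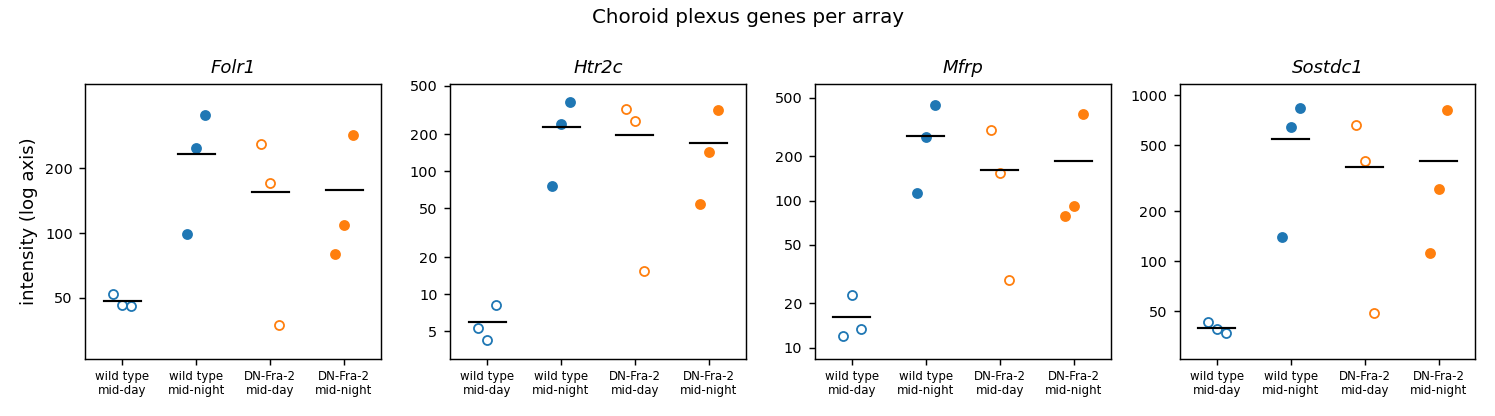
Intensity (log axis) of Folr1, Htr2c, Mfrp and Sostdc1 on each array by group. Each circle is an array (open by day, filled by night), each bar the mean of 3 arrays. The 3 wild-type mid-day arrays are low for all 4 genes, and the other groups are spread.

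In the list of cAMP-induced and immediate early genes, 15 of 17 measured members rose in wild type, none fell and 2 did not pass, the same number of rises when adjusted over the list alone, which also gave 1 fall. The examples Irs2, the orphan nuclear receptor gene Nr4a1 (6.71-fold), the cAMP-responsive transcription factor gene Crem (6.53-fold) and the phosphodiesterase gene Pde4b (3.14-fold) were among them, and the list was called higher by camera (adjusted p = 1.1e-16, and 0.00103 with an estimated correlation). Of 22 members of the adrenergic and cAMP signalling list, 8 rose, 1 fell and 13 did not pass (10 rose and 1 fell adjusted over the list alone), with Pde10a 8.95-fold and Drd4 7.39-fold higher. This list was called (adjusted p = 1.1e-05, and 0.00934 with an estimated correlation). Of 13 circadian clock genes, 8 rose and 2 fell, also adjusted over the list alone. Among them Cry2 was 3.41-fold, Per2 2.90-fold, Rorb 2.78-fold and Hlf 2.55-fold higher (list adjusted p = 1.1e-04, and 0.0165 with an estimated correlation). Of 17 endoplasmic reticulum (ER) chaperone and stress genes, 9 rose and none fell (11 adjusted over the list alone), led by the chaperone gene Hspa5 (3.28-fold) and Xbp1 (2.45-fold). That list was called too (adjusted p = 8.4e-07, and 0.0204 with an estimated correlation).

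Another 3 lists were called in wild type by camera with the preset correlation but not with an estimated one. By limma's fry all 3 were called (adjusted p = 4.8e-05, 8.0e-05 and 1.4e-04 in the order below). In the glucocorticoid response list 7 of 12 members rose and 1 fell (8 and 2 adjusted over the list alone). Dusp1 and Fkbp5 rose 8.30-fold and 2.25-fold, whereas Sgk1, which glucocorticoids induce in many tissues, fell by 1.77 on the log2 scale (list adjusted p = 8.6e-04; adjusted p = 0.0748 with an estimated correlation). In the heat shock list 6 of 11 members rose and 1, the heat shock factor gene Hsf1, fell (7 and 2 adjusted over the list alone), with Hsph1 2.20-fold higher. Its adjusted p was 0.00461 (adjusted p = 0.0643 with an estimated correlation). In the phototransduction list 9 of 19 members fell and none rose (12 fell and 1 rose adjusted over the list alone). Opn1sw, phosducin (Pdc), the rod channel gene Cnga1 and Gnb3 had log2 changes of −1.48, −0.91, −0.70 and −0.40 (list adjusted p = 0.00393; adjusted p = 0.142 with an estimated correlation).

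The other lists were not called by camera in wild type, though fry called some of them, melatonin synthesis included (adjusted p = 4.0e-06 by fry). Of 12 melatonin synthesis genes 4 rose and 1 fell, also adjusted over the list alone (list adjusted p = 0.0994). Mat2a, which makes the methyl donor of melatonin synthesis, rose 2.08-fold and 3.25-fold on its 2 probe sets, Asmt was at 976 ± 10.6 and 914 ± 20.5 (SD, n = 3, adjusted p = 0.424), and no probe set was annotated to Tph1. In the thyroid and retinoid list (adjusted p = 0.854) 2 of 13 rose, among them the deiodinase gene Dio2 (3.00-fold), and 3 fell. Of 11 pineal transcription factor genes (adjusted p = 0.499) 2 rose, Id1 1.80-fold and Crx 1.61-fold, and Isl2 fell by 1.18 on the log2 scale. In the lists of MAP kinase feedback (adjusted p = 0.0648), metal handling (0.108), AP-1 family (0.279), neurotransmitter and peptide receptor (0.176) and potassium channel genes (0.473), 3 of 5, 4 of 9, 2 of 4, 2 of 5 and 4 of 15 members rose. The copper transporter gene Atp7b (7.02-fold) and Fosl2 (2.99-fold) were among them, and 1 metal handling gene and 3 potassium channel genes fell. In the lists of cholesterol synthesis (adjusted p = 0.355), glycolysis (0.891), ribosomal protein (0.355), oxidative phosphorylation (0.135) and cell cycle genes (0.543), 2 of 10, 1 of 16, 1 of 38, 0 of 79 and 1 of 4 rose. In the same order, 0, 1, 0, 5 and 1 fell. Adjusted over the list alone the ribosomal and oxidative phosphorylation lists held no call. Of the 5 oxidative phosphorylation falls, those of Ndufb7, Cox7c, Sdhd and Ndufb3 were not called with Folr1 as a covariate (adjusted p = 0.0618 to 0.245), with log2 changes of −0.42, −0.32, −0.31 and −0.34 without it and −0.35, −0.29, −0.35 and −0.25 with it, and that of Atp5pf was lost without any 1 of 5 arrays. Over all lists, 107 probe sets were called in wild type, and 78 of them stayed called in all 12 fits without 1 array. With Folr1 as a covariate 34 of the 106 others than Folr1 were not called, and in DN-Fra-2 2 of 96. Of these 34, 32 kept at least 0.5 of their log2 change and 6 had a larger one, so the lost calls alone do not tie these genes to Folr1.

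Markers of cell types were mostly not called in wild type. Of 9 pinealocyte markers 3 rose and 2 fell (list adjusted p = 0.135), of 13 microglia and macrophage markers 1 rose (0.603), of 7 astrocyte markers 2 rose and 2 fell (0.854), and of 7 endothelial (0.542) and 14 fibroblast and meningeal markers (0.102) none changed. With Folr1 as a covariate none of the 4 astrocyte changes was called, but the log2 changes of S100b, Aqp4, Slc1a2 and Gja1 went only from 0.49, 0.50, −0.65 and −0.36 to 0.37, 0.35, −0.54 and −0.25. Of 3 neuronal markers Slc17a6, a glutamate transporter gene, rose 3.25-fold (list adjusted p = 0.473). Of 6 choroid plexus markers 2 rose, Folr1 3.48-fold and Prlr 5.55-fold, and Kcne2 fell by 0.57 on the log2 scale (list adjusted p = 0.210). The calls of Folr1, Prlr and Kcne2 were lost without any 1 of 5, 4 and 4 of the 12 arrays, and the first 2 also without filter. With Folr1 as a covariate the log2 change of Prlr was 0.23 (adjusted p = 0.695). Lists with fewer than 3 measured members had no set test. Of 2 oligodendrocyte markers Cnp fell by 0.69 on the log2 scale, and the 2 erythrocyte markers, the Schwann cell marker Pmp22, the muscle marker Myh1 and the sex-linked gene Xist had adjusted p values between 0.149 and 0.935.

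**Figure D2:**
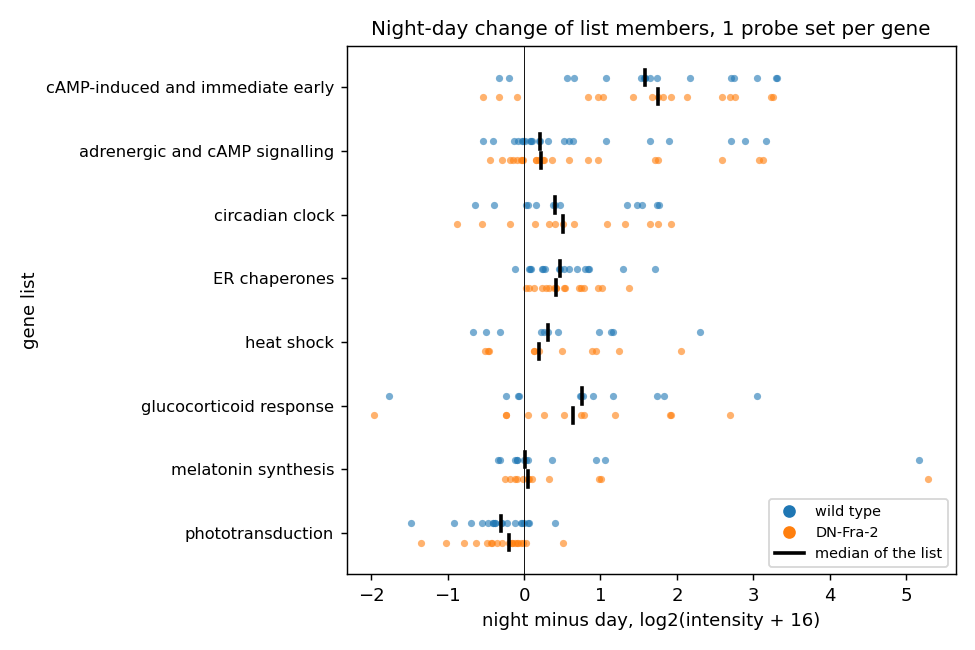
Night minus day change (log2 of intensity plus 16) of the members of 8 gene lists, 1 probe set per gene. Each dot is a gene, blue in wild type and orange in DN-Fra-2, and each black bar is the median of the list in that genotype. The medians of the cAMP-induced list lie above 1.5 in both genotypes and those of the phototransduction list below 0.

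The same night and day comparison was made in DN-Fra-2 rats. Aanat rose 38.9-fold, from 22.3 ± 3.57 to 1477 ± 158, and Slc15a1 by a log2 change of 4.91, from 17.4 ± 2.43 to 986 ± 82.0 (SD, n = 3). Irs2 rose 9.55-fold, Sik1 and Fcer1a each 9.42-fold, Drd4 8.74-fold and Pde10a 8.40-fold, followed by Cited4, Nap1l5 and Zrsr2-ps1. Hs3st2 had a log2 change of −2.82, Ptpn21 of −2.33 and Sgk1 of −1.96. Lnc215, Ndrg1, Hook1, Mrps27, the fatty acid import gene Cpt1a, Hspa12a and the guanylate cyclase subunit gene Gucy1a1 made up the other named falls, between −1.83 and −1.38. By limma 1586 probe sets changed, 789 higher and 797 lower at night, and at 2-fold or more 186 were higher and 68 lower. Crem (log2 changes of 3.24, 2.60 and 1.49), Nr4a1 (2.76), Dio2 (2.13), Per1 (1.92) and Mat2a (1.01 and 1.59) rose as well, while Asmt (0.07, adjusted p = 0.618) and Fosl2 (−0.09, adjusted p = 0.763) did not pass. The named genes had adjusted p values between 9.4e-13 and 8.7e-04.

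In DN-Fra-2, 14 of 17 cAMP-induced and immediate early genes rose and Fos fell by 0.54 on the log2 scale (14 and 2 adjusted over the list alone, list adjusted p = 4.1e-16, and 0.00117 with an estimated correlation). The adrenergic and cAMP list had 9 of 22 members higher and 1 lower (adjusted p = 3.4e-06, and 0.00695 with an estimated correlation), the clock list 8 of 13 higher and 2 lower (6.4e-05, and 0.0105) and the ER chaperone list 10 of 17 higher and none lower (1.4e-08, and 0.0105). Adjusted over the list alone these lists had 10, 9 and 12 higher members. Of 12 melatonin synthesis genes Aanat, Mat2a, Slc7a5 and Ddc rose, also adjusted over the list alone (list adjusted p = 0.0196; adjusted p = 0.130 with an estimated correlation). The call of Ddc was lost without DN-Fra-2 mid-night array 1 or 3 (adjusted p = 0.0679 and 0.0515) and when only the arrays compared were fitted (adjusted p = 0.0639). A second, dimmer probe set of Ddc had log2 changes of −0.72 in wild type (adjusted p = 0.0175) and −0.54 in DN-Fra-2 (adjusted p = 0.0822). Phototransduction genes had 9 of 19 members lower and the arrestin gene Sag higher (list adjusted p = 9.4e-04; adjusted p = 0.0861 with an estimated correlation), the same numbers adjusted over the list alone. Of 12 glucocorticoid response genes 6 rose and 1 fell (7 and 2 adjusted over the list alone, list adjusted p = 0.00144; adjusted p = 0.0861 with an estimated correlation). Of 11 heat shock genes 5 rose and 1 fell (6 and 2 adjusted over the list alone, list adjusted p = 0.0123; adjusted p = 0.0861 with an estimated correlation). In the MAP kinase feedback list Dusp1, Errfi1 and Dusp5 rose and Dusp6 fell, also adjusted over the list alone (list adjusted p = 0.0139; adjusted p = 0.205 with an estimated correlation). Of 5 neurotransmitter and peptide receptor genes the dopamine receptor gene Drd4, also in the adrenergic list, and the acetylcholine receptor gene Chrna3 rose (list adjusted p = 0.0405; adjusted p = 0.230 with an estimated correlation). The calls of Chrna3, Sag and Dusp6 were each lost without any 1 of 4 arrays, and that of Fos without 1 array. Chrna3 and Sag were also lost without filter, and Chrna3 and Dusp6 when only the arrays compared were fitted. The last 2 lists and melatonin synthesis were called by camera in DN-Fra-2 and not in wild type. The difference of the night change between genotypes was not called for any of them (adjusted p = 0.972, 0.445 and 0.637).

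Over both genotypes together the night change passed the test at 3082 probe sets, 1287 higher and 1795 lower. Among the probe sets called higher at night 632 were called in both genotypes, against 84.3 if the 2 sets of calls were independent, and among those called lower 617, against 108. No probe set was called in opposite directions. Across probe sets, which are not independent replicates, the night changes in the 2 genotypes correlated with Pearson's r = 0.863 and Spearman's rho = 0.774. Of the wild-type calls 97.1% had the same sign in DN-Fra-2.

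**Figure D3:**
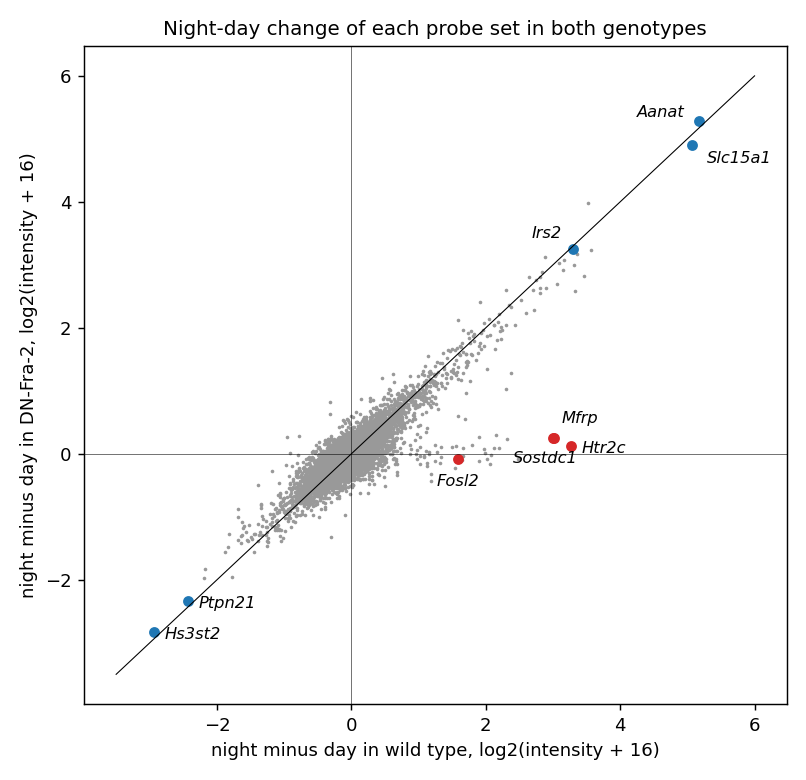
Night minus day change (log2 of intensity plus 16) of each of 8602 probe sets in wild type (horizontal) and in DN-Fra-2 (vertical). The line marks equal change. Aanat, Slc15a1, Irs2, Hs3st2 and Ptpn21 (blue) lie near the line, and Fosl2, Htr2c, Mfrp and Sostdc1 (red) lie near 0 in DN-Fra-2.

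Whether the night change differed between the genotypes was tested as an interaction. Fosl2 was the only gene called. In wild type its intensity rose from 15.6 ± 5.52 by day to 77.8 ± 4.81 by night, and in DN-Fra-2 it was 61.2 ± 9.66 by day and 56.7 ± 9.06 by night (SD, n = 3). The night change was smaller in DN-Fra-2 by a log2 difference of −1.67 (SE 0.22, adjusted p = 0.0210). The intervals of the difference included 0 for Aanat (−0.26 to 0.49, 95%), Nr4a1 (−0.36 to 0.39), Dio2 (−0.03 to 1.12) and each of the 3 Crem probe sets, and excluded a difference of 1 for the first 2 of these genes. At unadjusted p under 0.05 there were 341 probe sets. Htr2c, Mfrp and Sostdc1 had log2 differences of −3.15, −2.76 and −2.75 and did not pass, and Folr1 had one of −1.66.

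Among lists, 3 had a lower night change in DN-Fra-2 by camera. Of 4 AP-1 family genes Fosl2 was the one called, also adjusted over the list alone (list adjusted p = 0.0245; adjusted p = 0.216 with an estimated correlation), and without Fosl2 the list's adjusted p was 0.718. No astrocyte marker of 7 was called over all probe sets and 3 were lower adjusted over the list alone (list adjusted p = 0.00843; adjusted p = 0.216 with an estimated correlation). Aqp4, Gfap and S100b had log2 differences of −0.76, −0.61 and −0.48. No choroid plexus marker of 6 was called either way (list adjusted p = 0.00843; adjusted p = 0.706 with an estimated correlation). The call of Fosl2 was lost without filter, with replicate number as a block over all groups, with Folr1 as a covariate, and without any 1 of 8 arrays. These were each of the 3 wild-type mid-night arrays, DN-Fra-2 mid-day arrays 1 and 3, and each of the 3 DN-Fra-2 mid-night arrays, which each left 0 calls by limma. With the block within each time the call of Fosl2 was kept (adjusted p = 0.00917).

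The size of the night change was compared over the 3082 probe sets called in both genotypes together. In wild type 61.1% of them had the larger change, and the median change was 0.43 in wild type and 0.39 in DN-Fra-2, a ratio of 0.898. Among 100 assignments of genotype within each time, drawn from 200, 2 gave a share as far from an even split (permutation p = 0.02), the real one included. This p was 0.05 or more without wild-type mid-day array 1 (0.09) and without each DN-Fra-2 array, by day 0.40, 0.07 and 0.23 and by night 0.15, 0.25 and 0.37 for arrays 1, 2 and 3.

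DN-Fra-2 was compared with wild type at mid-day. Cox6a2, the muscle form of a cytochrome c oxidase subunit, was 3.07-fold higher in DN-Fra-2, at 227 ± 32.8 against 63.7 ± 16.9 (SD, n = 3). The serine synthesis genes Phgdh and Psat1 were 2.17-fold and 2.04-fold higher, at 221 ± 13.1 against 94.3 ± 19.6 and at 103 ± 8.81 against 42.3 ± 0.422. Slc7a3, a transporter of cationic amino acids, was 2.52-fold higher and Fosl2 2.45-fold. Opn1sw was lower in DN-Fra-2, at 75.1 ± 15.8 against 175 ± 32.5 (SD, n = 3). By limma 10 probe sets passed, 9 higher and 1 lower, with adjusted p between 0.00156 and 0.0405 and 429 at unadjusted p under 0.05. The others were Tmem221 (2.93-fold), the heme oxygenase gene Hmox1 (2.01-fold), the photoreceptor cadherin gene Cdhr1 (1.96-fold) and Gpnmb (1.51-fold), all higher. The count was 6 without wild-type mid-day array 1 and 2 with the stricter filter, and 16 when replicate number was a block within each time. Gpnmb was lost without any 1 of 10 of the 12 arrays and under 6 other settings, this block and Folr1 as a covariate among them. Cdhr1 was lost without any 1 of 8 arrays, without filter and with the stricter filter, and Hmox1 without any 1 of 5 and without filter. Opn1sw was lost without any 1 of 2 arrays, with the stricter filter and when only the arrays compared were fitted. The other 6 stayed called in all 12 fits without 1 array.

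Of 7 endothelial markers none was called over all probe sets by day and 4 were higher in DN-Fra-2 adjusted over the list alone. Plvap, which forms the diaphragms of fenestrated capillaries, Kdr, Vwf and Eng had log2 differences of 0.55, 0.52, 0.46 and 0.43, and the list was called higher (adjusted p = 6.1e-07, and 0.0114 with an estimated correlation). Of 4 AP-1 family genes Fosl2 was higher (2 adjusted over the list alone, list adjusted p = 1.3e-04, and 0.0274 with an estimated correlation), and of 17 cAMP-induced genes Fosl2 alone, also adjusted over the list alone (list adjusted p = 0.0160; adjusted p = 0.250 with an estimated correlation). Without Fosl2 both calls were lost (adjusted p = 0.0893 and 0.176). Of 19 phototransduction genes Opn1sw was lower and 5 were lower adjusted over the list alone (list adjusted p = 0.0159; adjusted p = 0.278 with an estimated correlation). In the ER chaperone (17 members), ribosomal protein (38), fibroblast (14) and choroid plexus (6) lists no gene was called either way, and the lists were called higher with adjusted p values of 0.0159, 0.0159, 0.0160 and 0.0160. With an estimated correlation these were lost (adjusted p = 0.278, 0.678, 0.493 and 0.493 with an estimated correlation). Folr1 was at 156 ± 112 in DN-Fra-2 and 48.3 ± 3.54 in wild type by day (SD, n = 3).

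At mid-night Cox6a2 was again 3.08-fold higher in DN-Fra-2, at 173 ± 60.0 against 43.7 ± 5.20 (SD, n = 3). Chac1, which degrades glutathione, was 2.36-fold higher, at 228 ± 22.5 against 87.2 ± 9.82, and Atf4, a transcription factor of the response to amino acid shortage, 1.48-fold, at a mean of 687 against 457. The calcium-binding protein gene Calb1 was 1.98-fold, Slc7a3 1.95-fold, the replication helicase gene Mcm7 1.72-fold and Fam171b 1.56-fold higher. Opn1sw was lower, at 19.4 ± 1.59 against 51.8 ± 3.62 (SD, n = 3), as were the lysosomal protease gene Ctsd with a log2 difference of −0.49 and 1 probe set with no listed gene, with −0.63 (chosen after values were seen). By limma 10 probe sets passed, 7 higher and 3 lower, with adjusted p between 0.00827 and 0.0452 and 463 at unadjusted p under 0.05. With replicate number as a block within each time, 16 passed and the 10 were kept. This was the only time at which every r between same-numbered arrays of the 2 genotypes was above 0.1. The count was 4 without wild-type mid-day array 3, 3, 0 and 1 without wild-type mid-night arrays 1, 2 and 3, and 1, 1 and 4 without DN-Fra-2 mid-night arrays 1, 2 and 3. It was 3 without filter, 6 with the stricter filter, 6 with a pseudocount of 64, and 1 when only the 6 mid-night arrays were fitted. None of the 10 calls was kept in all 12 fits without 1 array. Ctsd and the probe set with no listed gene were each lost in 11 of them, Mcm7 in 9, Opn1sw and Fam171b in 7, Atf4 in 6, Slc7a3 and Calb1 in 5, Chac1 in 4 and Cox6a2 in 1. Mcm7 and the probe set with no listed gene were also lost with Folr1 as a covariate (adjusted p = 0.0527 and 0.0562).

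By night 4 lists were called, and none with an estimated correlation. Of 19 phototransduction genes Opn1sw was lower and 3 were lower adjusted over the list alone (list adjusted p = 0.00254; adjusted p = 0.239 with an estimated correlation). No member passed over all probe sets in the microglia (13 members), astrocyte (7) and endothelial (7) lists, whose adjusted p values were 0.0135 (higher), 0.0223 (lower) and 0.0380 (higher). With an estimated correlation these were lost (adjusted p = 0.631, 0.239 and 0.239 with an estimated correlation). Adjusted over the list alone 1 astrocyte marker was lower, Gfap, at 90.7 ± 11.3 against 139 ± 19.7 (SD, n = 3).

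**Figure D4:**
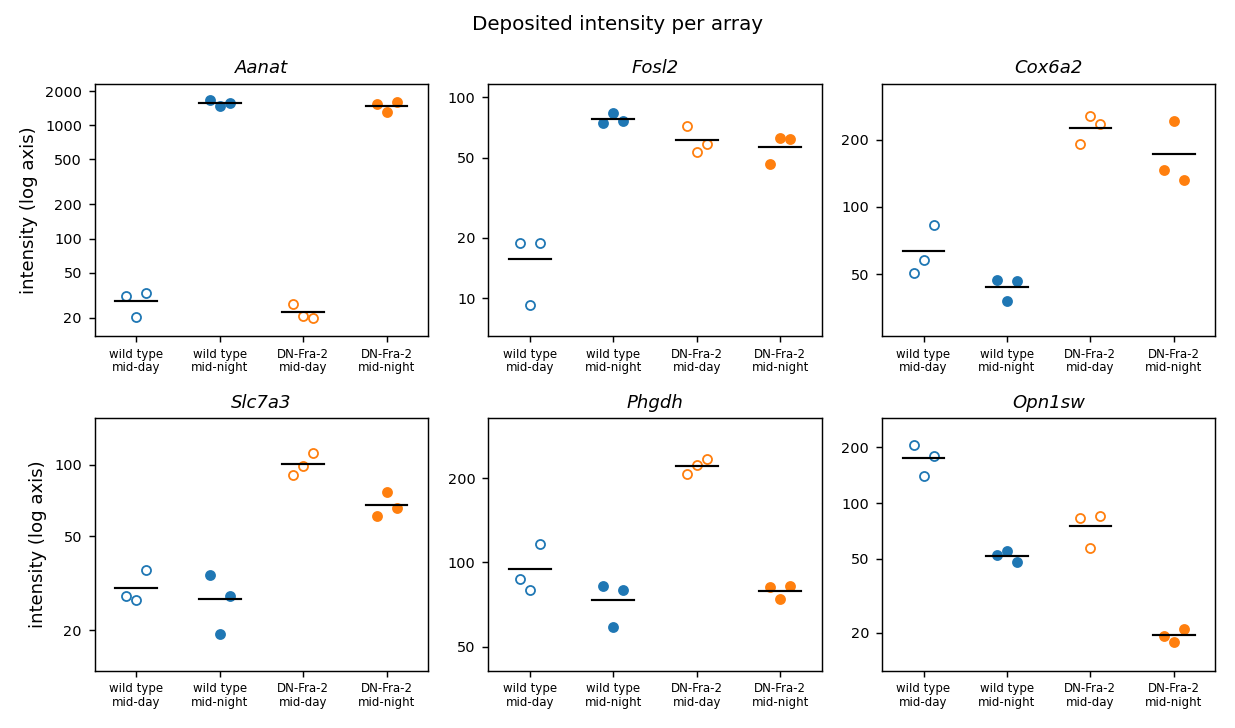
Intensity (log axis) of 6 genes on each array by group, with open circles by day, filled circles by night and a bar at the mean of 3 arrays. Cox6a2 and Slc7a3 are higher in DN-Fra-2 at both times, Phgdh by day, and Opn1sw is lower at both times, while Aanat overlaps between genotypes at night.

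Averaged over both times, 15 probe sets differed between DN-Fra-2 and wild type, 12 higher and 3 lower. Cox6a2 (3.07-fold), Slc7a3 (2.22-fold), Tmem221 (1.77-fold), Calb1 (1.72-fold), Hmox1 (1.70-fold), the G-protein signalling regulator gene Rgs4 (1.65-fold and 1.63-fold on its 2 probe sets), Chac1 (1.59-fold), Phgdh (1.52-fold), Psat1 (log2 difference 0.59), Gpnmb (1.49-fold) and Isoc1 (1.35-fold) were higher in DN-Fra-2. Opn1sw was lower (adjusted p = 5.2e-04), as were the rod channel subunit genes Cnga1 and Cngb1, with log2 differences of −0.58 and −0.37. Of these, Tmem221, Rgs4, Chac1, Phgdh, Psat1, Opn1sw, Cnga1 and Cngb1 fell outside the naming rule for this comparison and were chosen after values were seen. Adjusted p values by limma ran from 1.2e-04 for Cox6a2 to 0.0460 for a probe set of Rgs4, and 565 probe sets had an unadjusted p under 0.05. The melatonin synthesis genes Aanat and Asmt had log2 differences of −0.14 and −0.03 and did not pass (adjusted p = 0.880 and 0.980). The count was 9 without wild-type mid-day array 1 or 2, wild-type mid-night array 2 or DN-Fra-2 mid-day array 2, 8 without DN-Fra-2 mid-day array 3, and 28 with the block within each time, which kept the 15. Opn1sw, Cox6a2, Slc7a3, Tmem221, Calb1, Hmox1, Gpnmb and 1 probe set of Rgs4 stayed called in all 12 fits without 1 array. The other probe set of Rgs4 was lost in 10 of these 12 fits, Isoc1 and Psat1 in 8, Chac1 in 7 and Phgdh in 4 (adjusted p up to 0.176, 0.0819, 0.0819, 0.0856 and 0.0695). Cnga1 was lost without wild-type mid-day array 1 or 2, wild-type mid-night array 2, DN-Fra-2 mid-day array 2 or 3, or DN-Fra-2 mid-night array 2 (adjusted p = 0.0596, 0.0556, 0.0665, 0.0569, 0.0641 and 0.0529). Cngb1 was lost without trend (adjusted p = 0.0699), without filter, and without any 1 of 11 arrays (adjusted p = 0.0527 to 0.107), all but wild-type mid-day array 3 (adjusted p = 0.0484). A second, dimmer probe set of Cngb1 had a log2 difference of −0.35 over both times and did not pass (adjusted p = 0.314).

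Of 7 endothelial markers 5 were higher in DN-Fra-2 over both times adjusted over the list alone and none over all probe sets, with Plvap at a log2 difference of 0.48 and Eng at 0.37. This list was called (adjusted p = 3.2e-06, and 0.0163 with an estimated correlation). Of 19 phototransduction genes the 3 named above were lower, and 5 adjusted over the list alone (list adjusted p = 3.9e-04; adjusted p = 0.123 with an estimated correlation). No member of the AP-1 (4), cAMP-induced (17), ER chaperone (17), ribosomal protein (38) and microglia (13) lists was called over all probe sets, and 1, 1, 2, 0 and 0 were higher adjusted over the list alone. These lists were called higher with adjusted p values of 0.00138, 0.0108, 0.00138, 0.00761 and 0.00621, and the calls were lost with an estimated correlation (adjusted p = 0.0737, 0.125, 0.125, 0.732 and 0.487 with an estimated correlation). Without Fosl2 the AP-1 and cAMP-induced lists were not called (adjusted p = 0.0533 and 0.0699).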

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

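The splits of the arrays and the interaction tests reported here were planned, and the tests with Folr1 were chosen only after the result was seen.

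The night change of Fosl2 differed between genotypes by a log2 difference of −1.67 (adjusted p = 0.0210, limma). Fosl2 was higher by day in DN-Fra-2 (61.2 against 15.6) and lower by night (56.7 against 77.8), the latter not called. The wild-type mid-day values (9.27 to 18.9) lay near the pseudocount of 16. The annotation does not say whether its probe set also reads the transgene. By the same interaction test 3 gene lists had a lower night change in DN-Fra-2. They were the AP-1 family (adjusted p = 0.0245), whose call was lost without Fosl2 (adjusted p = 0.718), the astrocyte markers (adjusted p = 0.00843, median log2 difference −0.26) and the choroid plexus markers (adjusted p = 0.00843, median −0.29). None of the 3 was called with an estimated correlation (adjusted p = 0.216, 0.216 and 0.706). Chance was not excluded for either count. Of 100 regroupings drawn from 200, 16 called at least 1 probe set in the interaction, the highest other 42, and 31 called at least 3 lists, the highest other 10.

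The rise of Htr2c, Mfrp and Sostdc1 at night in wild type, not called in DN-Fra-2 and not different between genotypes by the interaction test without a covariate, was weighed as a pattern. Within groups the mean of the 3 genes followed Folr1 with Pearson's r = 0.995 (exact permutation p = 0.00386 over 1296 permutations), and 0.988 without the 2 arrays farthest from the median. With Folr1 as a covariate the mean wild-type night change fell from 3.09 (95% interval 0.88 to 5.31) to 0.69 (0.35 to 1.03), which argues against a night rise of these genes in pinealocytes alone. With it the mean night change in DN-Fra-2 was 0.03 (−0.23 to 0.28), the interaction −0.66 (−1.08 to −0.25) and the genotype difference at mid-day 0.84 (0.55 to 1.13). Without it the interaction was −2.89 (−6.01 to 0.24) and the mid-day difference 2.34 (0.13 to 4.55). On the wild-type mid-day arrays Htr2c was at 4.28 to 8.15, under the pseudocount of 16, while Folr1 hardly varied (46.0 to 52.4). The differences with the covariate may therefore in part reflect values near the floor. Choroid plexus tissue carried over with the glands in varying amounts may account for most of the rise, but the remaining 0.69 and the genotype difference found with the covariate stay open. A joint night rise of all these genes within the gland stays open too, since Folr1 was low on all 3 wild-type mid-day arrays and the covariate is in part confounded with time.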

How the results depend on the processing

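The Folr1 covariate, the block within each time, leaving out arrays for the lists and the lists without Fosl2 were tests chosen after the result was seen, and the others were planned. No result reversed. Moderation without trend kept each of the 7 counts of called probe sets within 1.5 times. Probe sets called for night against day in wild type were 2088, and 1248 with Folr1 as a covariate. For the interaction (1) there were 2 with a pseudocount of 1, 0 by limma without filter, with the 75th percentile filter (fewer probe sets tested), with a replicate block and with Folr1, against 341 at unadjusted p under 0.05 in the reported fit, and 0 to 1 when 1 array was left out. At mid-day (10) the stricter filter gave 2, the block within each time 16, and leaving out 1 array 6 to 9 (6 without wild-type mid-day array 1). At mid-night (10) a pseudocount of 64 gave 6, no filter 3, the stricter filter 6, only the arrays compared 1 and the block within each time 16. Leaving out 1 array gave 0 to 10: 4 without wild-type mid-day array 3, 3, 0 and 1 without wild-type mid-night arrays 1, 2 and 3, and 1, 1 and 4 without DN-Fra-2 mid-night arrays 1, 2 and 3. Over both times (15) the block within each time gave 28 and leaving out 1 array 8 to 14 (9 without wild-type mid-day array 1 or 2, wild-type mid-night array 2 or DN-Fra-2 mid-day array 2, and 8 without DN-Fra-2 mid-day array 3). The night change over both genotypes (3082) had 1935 with the stricter filter, which tests fewer probe sets. The agreement between genotypes (r = 0.863) was 0.785 without filter, 0.901 with the stricter filter and 0.805 to 0.869 without 1 array. The share with the larger change in wild type (61.1%, permutation p = 0.02) was 60.4% (permutation p = 0.05) after quantile normalization and 53.9% to 64.1% without 1 array. Lists called in wild type (7) were 4 with an estimated correlation, 15 with fry and 11 with Folr1, and in DN-Fra-2 (10) 4 with an estimated correlation. For the interaction (3) they were 0 with an estimated correlation and with fry, and 1 to 6 without 1 array (6 without wild-type mid-night array 1, 1 without DN-Fra-2 mid-night array 2). At mid-day (8) they were 2 with an estimated correlation, 2 with fry, 4 with Folr1 and 4 to 8 without 1 array (4 without DN-Fra-2 mid-day array 1, 5 without array 2). At mid-night (4) they were 0, 0 and 1 to 6 (2 without wild-type mid-night array 1, and 1 each without wild-type mid-night array 2 and DN-Fra-2 mid-night arrays 1 and 2), and over both times (7) 1 with an estimated correlation and 3 with fry. Where no reason is given the cause was not tested.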

Other observations

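The splits of the arrays were planned, and the comparison by pairs parted and the tests of the amino acid response and of the endothelial markers were chosen only after the result was seen.

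For comparisons of 3 arrays against 3 there are 10 splits, too few for a share under 0.05. The real split called 2088 probe sets in wild type (highest other 1), 1586 in DN-Fra-2 (0), 10 between genotypes at mid-day (1) and 10 at mid-night (1), and in each 1 of the 10 splits, the real one, gave as many. Of 100 regroupings drawn from 200, 1 gave as many as the 3082 calls for the night change over both genotypes (highest other 723), and 3 as many as the 15 calls between genotypes over both times (highest other 42). The share with the larger change in wild type (61.1%) was reached by 2 (highest other 61.7%) and the 7 lists called between genotypes by 2 (highest other 7). In the reported fit the fraction of regroupings that gave as much was under 0.05 for these 4 results, each taken alone. These fractions were not adjusted over the results tested this way, and the lists were those of the preset correlation. Regroupings also cannot tell genotype or time from other differences between the pools.

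For the share with the larger change the permutation p was not under 0.05 in several other fits. It was 0.05 after quantile normalization, 0.09 without wild-type mid-day array 1 and 0.07 to 0.40 without 1 DN-Fra-2 array. These regroupings ignore the pairs of same-numbered mid-night arrays. Of the 10 mid-night splits, 4 part all 3 pairs, too few for a share under 0.05, and the real one alone gave as many as its 10 calls (highest other 1). Of the 100 regroupings 41 part all 3 pairs, and the real one alone gave as many as its 15 calls (highest other 1) or 7 lists (highest other 6), while the highest with fewer pairs parted was 42 calls and 7 lists. The regroupings with 42 and 40 calls point to a structure of the samples: Folr1 differed 2.59-fold and 2.46-fold between their sides, and 33 and 30 of their calls followed Folr1 within groups with r above 0.9, against 0 of the real 15.

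Of 5 genes of the transcriptional response to amino acid shortage that were higher in DN-Fra-2, Phgdh and Psat1 differed by day (log2 1.12 and 1.03, by night 0.10 and 0.15), Chac1 and Atf4 by night (1.24 and 0.57, by day 0.10 and −0.06) and Slc7a3 at both times, and none of the 5 interactions passed. In a list of this response written after values were seen, 4 of 36 measured genes passed over both times and 31 had a positive difference (median log2 difference 0.16). The 5 genes were all the list members called between genotypes, so by definition none of the other 31 passed. Of these 31, 26 had a positive difference (median 0.12), and camera with an estimated correlation gave p = 0.00310. All 10 calls of list members were kept with Folr1 as a covariate, which argues against choroid plexus tissue carried over with the glands as the whole cause. All 10 were also kept with quantile normalization, but it changed no call between genotypes, so this check alone decides nothing. Over all probe sets the median genotype difference over both times was −0.003, and −0.001 after quantile normalization. The arrays were already scaled to a common level, so a median near 0 was largely fixed in advance and is no support in itself. The list without its called genes had a median of 0.12, and a shift common to all probe sets would not part it from the others. A scaling effect that depends on intensity is not addressed by these medians. A raised amino acid response in DN-Fra-2 glands is a candidate explanation, found and tested on the same data, which leaves the different times of these genes unexplained, and differences between pools of glands other than genotype remain untested.

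Endothelial markers were higher in DN-Fra-2 over both times (median log2 difference 0.27, Plvap 0.48, Eng 0.37). With Folr1 as a covariate the median was 0.274 (adjusted p = 3.5e-05, and 0.0428 with an estimated correlation), which argues against choroid plexus tissue carried over with the glands. The endothelial mean minus the astrocyte mean differed between genotypes by 0.30 (exact permutation p = 0.005, the smallest the 400 permutations can give). This argues against a lower share of pinealocytes raising endothelial and astrocyte markers alike. The astrocyte mean itself was lower in DN-Fra-2 (−0.04), while the microglia (0.13) and fibroblast means (0.07) were higher. The pinealocyte mean was not lower (0.06, exact permutation p = 0.23). The difference of the endothelial mean was 0.19 against fibroblast markers (exact permutation p = 0.03) and 0.13 against microglia markers (exact permutation p = 0.225). A larger share of vessel tissue in the pools or a higher level of these genes per cell may account for the higher endothelial markers, and neither was tested.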
